A study of Homo sapiens with 60 samples.

How the data were processed

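HEK293A cells carrying a TDP1 knockout, as 3 clones (C6, F7 and G6), were grown in DMEM/F12 with 10% fetal bovine serum and treated for 5 to 5.5 hours. Per the labels, topotecan was given in 0.1% DMSO and OL9-119 was dissolved in 0.1% DMSO, and for the combination the label names no DMSO. RNA was taken with Trizol, poly(A) RNA was enriched, and libraries were made with a directional kit. Each of 15 groups (3 clones by 5 treatments) had 4 biological replicates, 60 libraries in all. The deposited table holds counts, whole numbers per Ensembl gene and library, which the authors had not normalised. The submitters' processing notes name FastQC 0.11.9, STAR 2.7.8, Picard 2.26.6 and the genome build hg38. The counting tool, annotation release and strand setting are not given in the sources used here, so statements on mitochondrial strands rest on the annotated strand of each gene.

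The table held 58395 gene identifiers, of which 58275 were found in GENCODE 29 and 57754 had a symbol in the table of current gene names. The 120 not in GENCODE 29 held 0.0052% of the counts. Totals ran from 4.62 to 20.9 M counts per library (median 11.4 M counts), detected genes from 17480 to 29092, the mitochondrial share from 3.15 to 6.72%, and the share of the 50 highest genes from 10.7 to 14.4%. TMM factors lay between 0.925 and 1.08. At these depths a gene at 1 CPM holds about 5 to 21 counts per library. Between replicates the variance of the counts was 2.31 to 58.9 times that of counting error (chi-square per degree of freedom over 90 pairs). Intervals and floors given for low counts cover counting error only.

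Genes past filterByExpr on the 15 groups (18985) were tested with edgeR 4.0.16 (quasi-likelihood F test, 2-sided, TMM scaling) in R 4.3.3, in a model with 1 mean per group fitted to all 60 libraries. Treatment comparisons average the differences within the 3 clones. The comparisons were topotecan, OL9-119 and the combination, each minus DMSO, the combination minus each compound alone, DMSO minus no treatment, the interaction on the log2 scale, the 3 pairs of clones in DMSO, and the dependence of each treatment on the clone (F test over the 3 clones). Adjusted p are Benjamini-Hochberg values over genes within a comparison, with a threshold of 0.05. A value after ± is an SE beside a log2 change and an SD beside a level. CPM values (counts scaled to a common library total) use TMM effective library sizes, and log2 values for display use a prior count of 2.

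Named genes follow a rule fixed before the data were examined. TDP1 and TOP1 are always named. For topotecan, OL9-119 and the combination minus DMSO and for the combination minus topotecan, the 10 highest and 10 lowest log2 changes are named among genes past the threshold with a mean log2 CPM of at least 2, the same sign in all 3 clones and an established symbol. For other comparisons 5 of each are named, and for clone dependence the 5 smallest p. Of each gene list that passed, or had at least 3 passing members, up to 4 passing members with the smallest p could be named. Genes on chromosome 14 near TDP1 and the mitochondrial genes are described in addition.

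The 30 gene lists were fixed before the data were examined: p53 targets, immediate early genes, replication-dependent histones, TOP1 lesion and single-strand break repair, homologous recombination and Fanconi anaemia, G1/S and replication, G2/M and mitosis, NF-kB targets, interferon-stimulated genes, the unfolded protein response, ATF4 and the integrated stress response, NRF2 targets, heat shock, sterol and lipid synthesis, HIF1 targets and glycolysis, mitochondrially encoded mRNAs, nuclear-encoded oxidative phosphorylation, cytosolic ribosomal proteins, ribosome biogenesis, apoptosis regulators, aryl hydrocarbon receptor targets, metallothioneins, splicing SR proteins and CLK kinases, chromatin and topoisomerases, extracellular matrix, neuronal and renal lineage genes, nuclear-retained and non-coding RNAs, and markers of blood cells, fibroblasts and hepatocytes. They were tested with camera in limma 3.58.1 (preset correlation 0.01, 2-sided), again with an estimated correlation, and with fry, and adjusted over the lists within a comparison. A list is described as passing where camera with the preset value passed.

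Gene span is the distance from start to end in GENCODE 29. The slope on log10 span was taken in each of the 12 combinations of clone and replicate number, and partial rank correlations hold exon length, exon number, GC content and mean expression fixed. Chromosome medians between clones were set against 10000 random gene sets of the same size. Mitochondrial strands were compared by permuting strand over genes 100000 times. Treatments were compared with splits of the libraries that mix the groups, in fits of only the groups compared. Detected genes were compared at a common depth of 4.5 M counts, and leaving out the 14 libraries under 20000 genes was added after seeing the data.

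Alternatives fixed before the data were examined were other low-count filters (none, or CPM of at least 1 in 12 libraries), DESeq2 1.42.0 as the test, DESeq2 size factors in the edgeR fit, the prefix of the library code as a covariate, replicate blocks, untreated libraries in place of DMSO, fits of only the groups compared, 2 clones in place of 3, and leaving out each replicate number and each library in turn. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

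The steps were tested on simulated data with planted changes. For topotecan minus DMSO, 75% of 68 genes planted at log2 0.5, 98.5% of 66 at log2 1 and 98.5% of 66 at log2 2 were called, and 9 of 190 calls were false. For C6 minus F7 the shares were 27.9, 81.8 and 97%, with 2 of 139 calls false. For the clone dependence of OL9-119, 66.5% of 200 genes planted at log2 1 were called, with 10 of 143 calls false, and DMSO minus no treatment gave 0 calls with nothing planted. Genes were drawn independently, with no factor shared within a library beyond its size. These shares thus do not cover false calls from low gene detection in whole libraries. A slope planted at -0.2 per 10-fold span came back as -0.192, and a chromosome 20 median planted at -0.6 as -0.6. In the simulated data with this slope and a shift of the NF-kB targets planted, 8 of the 30 lists passed camera with the preset correlation, so that a trend with gene span by itself moves lists of short or long genes past that threshold.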

Results

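RNA was sequenced from 60 libraries of HEK293A cells, a human embryonic kidney line, in which the TDP1 gene had been targeted for knockout. TDP1 removes the stalled topoisomerase 1 protein that topotecan traps on DNA. The libraries came from 3 knockout clones named C6, F7 and G6. Each clone was left untreated, or was given DMSO at 0.1%, topotecan at 100 nM, the compound OL9-119 at 5 µM, or topotecan and OL9-119 together. OL9-119 is one of the compounds developed against the TDP1 enzyme. There were 4 biological replicates per clone and treatment, so that each treatment had 12 libraries. No unedited parental library was used here, so a difference caused by the knockout itself was not measured. The total per library ran from 4.62 to 20.9 M counts (median 11.4 M counts).

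In 14 libraries fewer genes were detected than in the rest when all libraries were reduced to 4.5 M counts. These held 17454 to 19345 detected genes, and the other 46 held 20160 to 23640. Of the 14, 10 came from clone C6 and 4 from clone G6. They fell on every treatment, with 2 untreated, 3 DMSO, 2 topotecan, 3 OL9-119 and 4 combination libraries. Their totals (4.62 to 16.8 M counts) overlapped those of the others (5.22 to 20.9 M counts). Counts of changed genes are also given below without them, a comparison chosen after seeing the data. That fit applied the low-count filter anew and tested more genes (2043 against 1883 on chromosome 1). Its counts are thus not out of the same 18985 genes.

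TDP1 itself (ENSG00000042088, chromosome 14, 89954939 to 90044768, hg38) was counted in all 60 libraries, at 17.8 to 42.2 CPM (counts scaled to a common library total). An edited exon can leave the whole-gene poly(A) count in place, so these counts do not test the knockout. In DMSO the level was 36.2 ± 3.52 CPM in clone C6, 26.7 ± 2.31 CPM in F7 and 32.2 ± 5.37 CPM in G6 (SD, n = 4). Clone C6 lay above F7 by 0.44 ± 0.12 on the log2 scale (adjusted p = 0.00254, edgeR quasi-likelihood). Topotecan lowered TDP1 counts by a log2 change of -0.37 ± 0.07 (adjusted p = 5.3e-05, edgeR), from a mean of 31.7 to 24.8 CPM over 12 libraries each. OL9-119 left TDP1 at 31.4 CPM, a log2 change of 0.00 ± 0.07 (adjusted p = 0.986, edgeR). The combination gave 26.6 CPM, a log2 change of -0.24 ± 0.07 (adjusted p = 0.00745, edgeR). TOP1 (ENSG00000198900, chromosome 20, 41028818 to 41124487), which encodes the enzyme that topotecan traps, stood in DMSO at 300 ± 35.8 CPM in C6, 428 ± 28.8 CPM in F7 and 491 ± 78.0 CPM in G6 (SD, n = 4). It was lower in C6 than in F7 (log2 -0.51 ± 0.12, adjusted p = 0.000352, edgeR) and than in G6 (-0.71 ± 0.12, adjusted p = 4.15e-06, edgeR). Topotecan lowered TOP1 by -0.28 ± 0.07 (adjusted p = 0.00135, edgeR) and the combination by -0.31 ± 0.07 (adjusted p = 0.000311, edgeR).

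**Figure D1:**
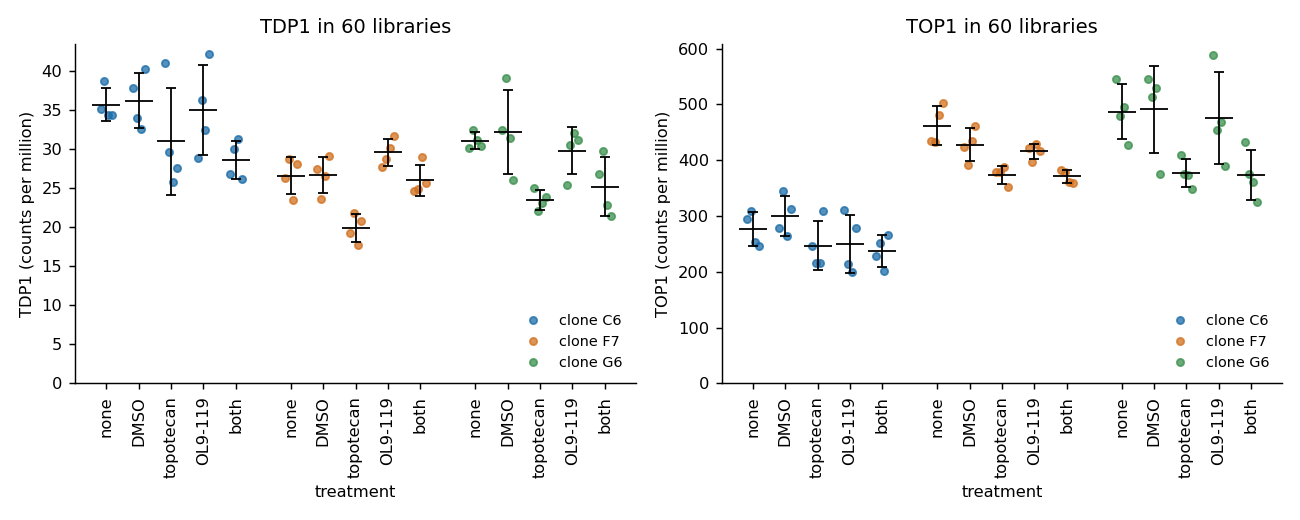
TDP1 and TOP1 in CPM (linear axes from 0) in every library, by clone and treatment, with bars at the mean of 4 replicates and SD. TDP1 was counted in all 60 libraries, and TOP1 was lower in clone C6 (300 CPM in DMSO) than in F7 (428 CPM) and G6 (491 CPM).

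Topotecan against DMSO asks which transcripts respond to trapped topoisomerase 1 in cells whose TDP1 gene was targeted. CXCL8 (chromosome 4, 73740506 to 73743716), which encodes the chemokine interleukin-8, rose 5.91-fold (log2 2.56 ± 0.14, adjusted p = 1.04e-21, edgeR, n = 12 libraries per treatment). CCL20, another chemokine, rose 3.59-fold, and TNFAIP3, whose product limits NF-kB signalling, rose 3.50-fold (log2 1.81 ± 0.06, adjusted p = 1.65e-30, edgeR). PTX3 (log2 1.46), TNFRSF9 (1.22), TCIM (1.18), IER3 (1.18), the NF-kB subunit gene RELB (1.16), the non-coding HCP5 (1.15) and NFKBIA, which encodes an inhibitor of NF-kB (1.12), complete the 10 largest increases. At the other end stood NCKAP5 (log2 -1.50 ± 0.19, adjusted p = 1.73e-08, edgeR), PIF1, which encodes a DNA helicase (-1.32), CDK14 (-1.27), FOXP2 (-1.26), NLGN1 (-1.24), TTC28 (-1.23), GRIP1 (-1.21), KCNQ5 (-1.21), HS6ST3 (-1.16) and PTPRD (-1.15). Of these 10, all but PIF1 (10.0 kb) span at least 577 kb of the genome, and PTPRD spans 2300 kb. In all, 2913 of 18985 genes passed the threshold, 1138 higher and 1775 lower (1330 and 1454 with no filter), of which 2868 had the same sign in all 3 clones. Genes pass on the mean over the clones, which favours the same sign, so this count is not a replication across clones. Without the 14 low-detection libraries 3823 genes passed.

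Of the 30 gene lists fixed before the data were examined, 8 passed camera with a preset correlation after topotecan and 6 of these also passed with an estimated correlation. Of 22 NF-kB targets 20 rose, none fell and 2 did not pass, with 21 higher when adjusted over the list alone (median log2 0.75, adjusted p = 4.68e-10 with an estimated correlation). Of 30 immediate early genes 18 rose, 1 fell and 11 did not pass, with 22 higher and 1 lower when adjusted over the list alone (median 0.30, adjusted p = 5.3e-05 with an estimated correlation), among them the transcription factor genes ATF3 (log2 0.94) and JUN (0.91) and the phosphatase gene DUSP1 (0.58). Of 30 G2/M and mitosis genes 28 fell, also when adjusted over the list alone, and 2 did not pass (median -0.61, adjusted p = 4.33e-08 with an estimated correlation). They included the kinase gene AURKA (-0.85), the cyclin gene CCNB1 (-0.59), the spindle checkpoint gene BUB1B (-0.70) and the centromere histone gene CENPA (-0.91). Of 34 G1/S and replication genes 21 rose, 1 fell and 12 did not pass, with 27 higher and 1 lower adjusted over the list alone (median 0.24, adjusted p = 2.38e-07 with an estimated correlation). The replication licensing genes CDC6 (0.45) and MCM4 (0.32) rose, and POLA1, a DNA polymerase gene, fell (-0.41). Of 32 targets of ATF4 and the integrated stress response 15 rose, also when adjusted over the list alone, and 17 did not pass (median 0.18, adjusted p = 0.00686 with an estimated correlation), led by PPP1R15A (0.70). Of 30 p53 targets 9 rose and 21 did not pass, with 12 higher and 1 lower adjusted over the list alone (median 0.15, adjusted p = 0.00111 with an estimated correlation), led by GADD45A (0.74). Mitochondrially encoded mRNAs (median -0.14, none of 13 passing by edgeR, adjusted p = 0.733 with an estimated correlation) and ribosome biogenesis (5 up and 1 down of 30, adjusted p = 0.358 with an estimated correlation) passed only with the preset value. In simulated data where the NF-kB targets and a slope on gene span were planted, 8 lists passed with the preset value as well. Immediate early genes and ATF4 targets were among them, so the preset test does not separate these 2 lists from the trend with gene span described below. Their medians (0.30 and 0.18) lay above the 0.12 of genes under 10 kb, of which 12.6% rose. The medians of p53 targets (0.15) and ATF4 targets lay within the quartiles of those genes (0.01 to 0.24). That of G1/S genes (0.24) lay at the upper quartile. The size of these medians thus does not set the lists apart from genes under 10 kb.

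The other 22 lists did not pass camera after topotecan (adjusted p from 0.0649 to 0.882). Within them, the interferon-stimulated genes had 6 members up and 2 down of 30, IRF1 rising most clearly (log2 0.85). Splicing SR proteins and CLK kinases had 5 up and 1 down of 18, with SRPK2 at -0.55, and chromatin and topoisomerases had 1 up and 5 down of 19, with TOP2A at -0.63. Nuclear-retained and non-coding RNAs had 4 up and 3 down of 11, with SNHG1 at 0.42 and NEAT1 at -0.45, and here the median (-0.12) and mean (-0.05) lay below 0 while camera pointed up. TOP1 lesion repair had 2 up and 4 down of 25, XRCC4 at -0.58 among them, and homologous recombination with Fanconi anaemia 3 up and 4 down of 27, FANCC at -0.43 and EXO1 at 0.44. Apoptosis regulators had 4 up and 2 down of 25, sterol and lipid synthesis 3 up and 1 down of 26, NRF2 targets 3 up and 2 down of 24, and the unfolded protein response 2 up and 1 down of 24. The extracellular matrix list had 1 up and 3 down of 25 and the neuronal and renal lineage list 2 up and 2 down of 24. Heat shock (22 members), HIF1 targets (30), metallothioneins (7) and markers of blood cells (9) had 1, 2, 1 and 1 members down and none up. No member passed by edgeR among 17 replication-dependent histones, 30 nuclear-encoded oxidative phosphorylation genes, 30 cytosolic ribosomal proteins, 9 aryl hydrocarbon receptor targets, 8 markers of fibroblasts and the 1 marker of hepatocytes that passed the filter.

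Long genes were lower after topotecan. Trapped topoisomerase 1 is known to hinder elongation along long transcription units. Across 14685 protein-coding genes the rank correlation of log2 change with genomic span was -0.49, and genes are not independent replicates. Of 1176 genes spanning over 200 kb 668 fell and 1 rose (median -0.36). Of 2857 genes under 10 kb 361 rose and 32 fell (median 0.12). The bins between had medians of 0.09 (4071 genes of 10 to 30 kb), -0.01 (4774 of 30 to 100 kb) and -0.16 (1807 of 100 to 200 kb). The slope on log10 span was below 0 in 12 of 12 differences between libraries of the same clone and replicate number (mean -0.229, SD 0.132, from -0.486 to -0.025), against a background slope, DMSO minus untreated, of -0.0307 (SD 0.105, from -0.261 to 0.135), which was below 0 in 8 of 12. In C6 replicate 4 the background (-0.261) was steeper than topotecan (-0.025). Both slopes use the same DMSO library with opposite sign, so they are not independent. An exact sign-flip permutation over the 3 clones gave p = 0.25, 2-sided, the smallest that 3 clones allow. With exon length, exon number, GC content and expression level held fixed, the partial rank correlation was -0.28. The rank correlations by clone were -0.36 in C6, -0.40 in F7 and -0.49 in G6. Among genes with a mean log2 CPM of at least 4 it was -0.63, and without the low-detection libraries -0.47.

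**Figure D2:**
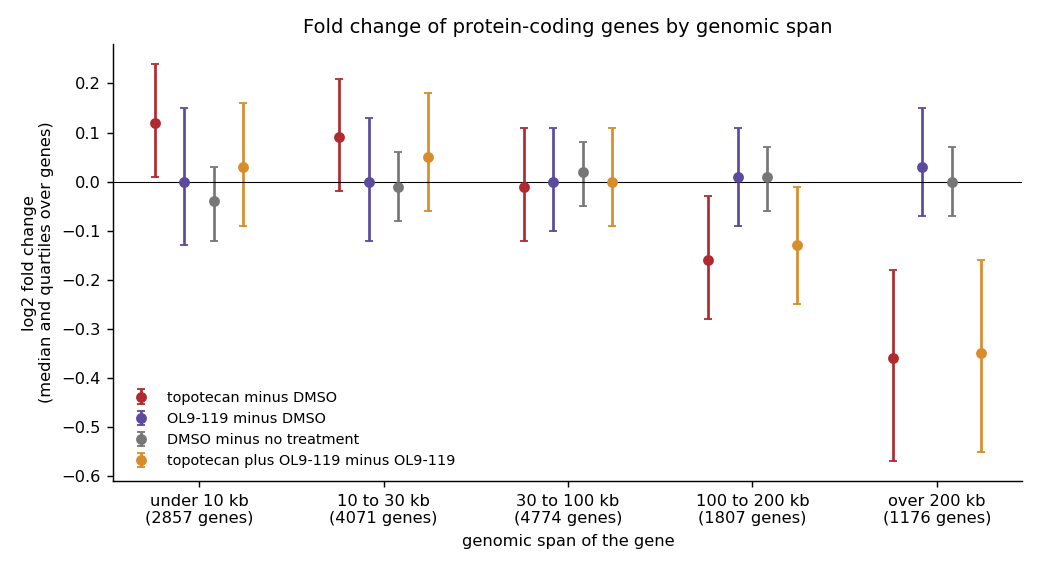
Log2 fold change of 14685 protein-coding genes in 5 bins of genomic span, as medians with quartiles, for topotecan and OL9-119 (each minus DMSO), DMSO minus no treatment, and the combination minus OL9-119. After topotecan the median goes from 0.12 under 10 kb to -0.36 over 200 kb.

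OL9-119 against DMSO asks what the compound does to transcripts in cells whose TDP1 gene was targeted. Genes of the integrated stress response rose most. CHAC1 (chromosome 15, 40952962 to 40956519), which encodes a glutathione-degrading enzyme, rose 8.08-fold (log2 3.01 ± 0.17, adjusted p = 1.78e-21, edgeR, n = 12 libraries per treatment), from 5.22 to 42.7 CPM. The cystine transporter gene SLC7A11 rose 3.54-fold (log2 1.82 ± 0.10, adjusted p = 1.13e-20, edgeR), the glycine transporter gene SLC6A9 3.42-fold, DDIT4, an inhibitor of mTORC1, 3.18-fold, and DDIT3, which encodes the transcription factor CHOP, 2.92-fold. GDF15 (log2 1.40), PCK2 (1.35), CEBPB (1.32), STC2 (1.28) and JDP2 (1.23) complete the 10 largest increases. The 10 largest decreases were the mitochondrial genes MT-TQ, MT-TP, MT-ND5, MT-ND6 and MT-ND3, the chaperone genes HSPA1B (log2 -1.09), HSPA8 (-1.08 ± 0.04, adjusted p = 6.9e-27, edgeR, from 1180 to 574 CPM) and HSPE1 (-0.73), and FGFBP1 (-1.04) and GBP1 (-0.70). HSPA1B has the near-identical copy HSPA1A, so the division of reads between them is uncertain. In all, 1798 genes passed, 849 higher and 949 lower, of which 71 changed at least 2-fold and 1758 had the same sign in all 3 clones, which passing on their mean favours. Without the low-detection libraries 2820 passed. The span of genes had almost no relation to the change (rank correlation 0.02 across genes). For OL9-119 added to topotecan it was 0.24, and 0 as a partial rank correlation.

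After OL9-119, 10 lists passed camera with the preset correlation and 7 of these with an estimated one. Of 32 ATF4 and integrated stress response genes 31 rose and 1 fell, also when adjusted over the list alone (median log2 0.76, adjusted p = 5.32e-14 with an estimated correlation), TRIB3 (1.22) among them. Of 22 heat shock genes 15 fell, 17 when adjusted over the list alone (median -0.24, adjusted p = 9.28e-07 with an estimated correlation), with the co-chaperone genes DNAJB1 and DNAJA1 both at -0.48. Of 13 mitochondrially encoded mRNAs 12 fell, 13 when adjusted over the list alone (median -0.50, adjusted p = 0.00107 with an estimated correlation). Of 30 nuclear-encoded oxidative phosphorylation genes 8 fell, also when adjusted over the list alone (median -0.13, adjusted p = 0.0368 with an estimated correlation), NDUFA4 (-0.29) and COX6C (-0.27) among them. Of 30 G2/M genes 8 fell, 12 when adjusted over the list alone (median -0.14, adjusted p = 0.0283 with an estimated correlation), KIF20A at -0.35. Of 22 NF-kB targets 5 rose and 1 fell, 9 and 2 when adjusted over the list alone (median 0.23, adjusted p = 0.0407 with an estimated correlation), NFKBIA at 0.37. Of 11 nuclear-retained and non-coding RNAs 3 rose and 2 fell, 5 and 2 when adjusted over the list alone (median 0.14, adjusted p = 0.0407 with an estimated correlation): SNHG1 (0.56), GAS5 (0.42) and NEAT1 (0.36) rose and TUG1 (-0.18) fell. Without the low-detection libraries the estimated-correlation test no longer passed for the oxidative phosphorylation (adjusted p = 0.229), NF-kB (0.105) and nuclear-retained and non-coding RNA (0.246) lists.

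The preset correlation alone passed homologous recombination and Fanconi anaemia (4 up of 27, adjusted p = 0.326 with an estimated correlation), HIF1 targets (1 up and 5 down of 30, VEGFA at 0.68 and LDHA at -0.27, adjusted p = 0.42 with an estimated correlation) and cytosolic ribosomal proteins (2 down of 30, adjusted p = 0.534 with an estimated correlation). Of the lists that did not pass camera, the aryl hydrocarbon receptor targets had CYP1B1 (log2 -0.63), CYP1A1 (-0.54) and TIPARP (-0.52) down and the amino acid transporter gene SLC7A5 (0.61) up. The unfolded protein response had 3 up, HERPUD1 (0.99) and XBP1 (0.84) among them, and 4 down of 24, with a median of -0.06 and a mean of 0.02. Immediate early genes had 8 up and 5 down of 30, ATF3 (0.72) and JUN (0.50) up and the matricellular genes CCN1 (-0.65) and CCN2 (-0.64) down. The p53 targets had 4 up and 6 down of 30, SESN2 (1.08) up and RPS27L (-0.40) down, with a median of -0.01 and a mean of 0.04. SESN2 and GDF15, both higher, are on the ATF4 list as well, as is SLC7A5.

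Most mitochondrial transcripts were lower after OL9-119, with a lower median for genes annotated on the minus strand. All 7 minus-strand genes tested fell (median log2 -3.87). Of 17 plus-strand genes 13 fell and 1 rose (median -0.45). The difference of medians, -3.42, had a permutation p of 0.00053 (2-sided, 100000 permutations of the strand over the genes, which are not independent replicates). Strand is mixed with RNA type here, since 6 of the 7 minus-strand genes are transfer RNAs and 3 of the 17 plus-strand genes are. Of those 3, MT-TT fell, and MT-TI (log2 -0.43 ± 0.38, adjusted p = 0.593, edgeR) and MT-TW (0.35 ± 0.30, adjusted p = 0.568, edgeR), both near 1 CPM, did not pass. MT-ND6, the only minus-strand mRNA, which encodes a complex I subunit, fell from 540 to 169 CPM (log2 -1.68 ± 0.16, adjusted p = 1.31e-12, edgeR, n = 12). The transfer RNA genes MT-TQ and MT-TP fell from 7.36 to 0.566 CPM and from 12.6 to 1.15 CPM. The libraries were enriched for poly(A) RNA, so these counts do not separate the amount of a mitochondrial RNA from its capture. Of the 7, 2 had at most 3 counts over all OL9-119 libraries, and with these set to 3 counts the median was still -3.87. On the plus strand MT-ND5, which ends beside MT-ND6, fell most among the mRNAs, further than MT-ND6 (2480 to 610 CPM, log2 -2.06 ± 0.09, adjusted p = 9.31e-27, edgeR), MT-ND3 fell by 1.05 on the log2 scale, and MT-TT, beside MT-TP, fell from 1.08 to 0.0999 CPM. The ribosomal RNA gene MT-RNR1 rose from 2610 to 4530 CPM (log2 0.75 ± 0.07, adjusted p = 9.49e-12, edgeR). With topotecan present, OL9-119 gave a minus-strand median of -4.22. After topotecan alone no mitochondrial gene passed by edgeR, and the smallest adjusted p among the mRNAs was 0.0833, for MT-ND4L. The mitochondrial share of counts was 5.23 ± 0.81% in DMSO and 4.21 ± 0.68% after OL9-119 (SD, n = 12).

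**Figure D3:**
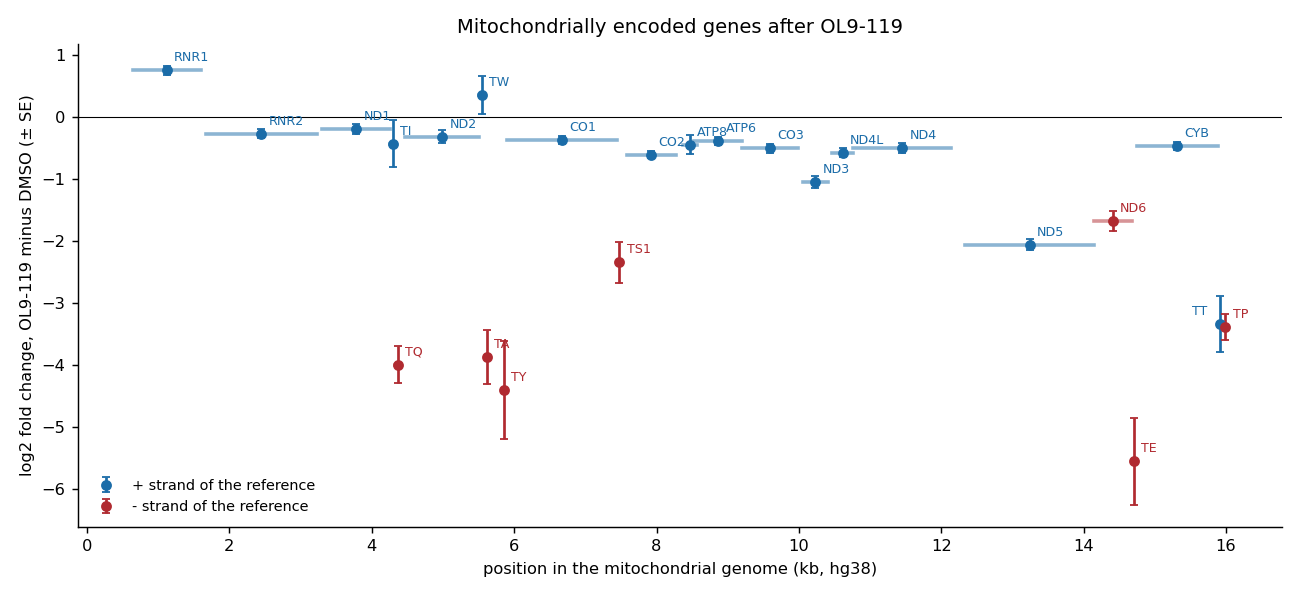
Log2 fold change of each mitochondrially encoded gene, OL9-119 minus DMSO, against its position in the mitochondrial genome (kb), coloured by annotated strand, with bars for SE. The 7 minus-strand genes lie at -1.68 or lower, and MT-RNR1 lies at 0.75.

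The combination against DMSO asks what both compounds do together. It changed 4033 genes, 1808 higher and 2225 lower, 204 of them at least 2-fold (1971 higher and 2069 lower with DESeq2 size factors). With the low-detection libraries left out, 4335 passed. CHAC1 (log2 2.91 ± 0.17), CXCL8 (2.63 ± 0.14), CCL20 (2.24 ± 0.17), TCIM (1.94), TNFAIP3 (1.91), SLC6A9 (1.79), C11orf96 (1.67), PTX3 (1.65), TNFRSF9 (1.52) and NFKBIA (1.44) rose most. MT-TQ (-4.27), MT-TP (-3.00), MT-ND5 (-1.96), MT-ND6 (-1.83), NCKAP5 (-1.49), HSPA1B (-1.43), the Notch coactivator gene MAML3 (-1.36), TTC28 (-1.25) and PIF1 (-1.24) fell most, with ARMCX4, which was near 0 in clone F7. Of 14 lists past the preset correlation 8 also passed with an estimated one. ATF4 targets had 30 of 32 up (median 0.86, adjusted p = 2.92e-10 with an estimated correlation) and NF-kB targets 20 of 22 up (median 0.70, adjusted p = 4.47e-10 with an estimated correlation). G2/M genes had 27 of 30 down (median -0.59, adjusted p = 1.58e-06 with an estimated correlation), heat shock 16 of 22 down (-0.27, 0.000175), and mitochondrially encoded mRNAs 12 of 13 down (-0.50, 0.0144). Immediate early genes had 15 up and 2 down of 30 (0.32, 0.00206), G1/S genes 16 up and 2 down of 34 (0.15, 0.000655) and p53 targets 9 up and 2 down of 30 (0.11, 0.000606). Lost with an estimated correlation were homologous recombination (adjusted p = 0.348), interferon-stimulated genes (0.143), oxidative phosphorylation (0.244) and ribosomal proteins (0.601). Splicing factors (0.244, 10 up and 4 down of 18, SRSF6 at 0.56) and nuclear-retained and non-coding RNAs (0.0609, SNHG1 at 0.86) were lost as well.

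Adding OL9-119 to topotecan changed 1287 genes, 632 higher and 655 lower, and 859 without the low-detection libraries. Which direction held more genes depended on scaling and filter (698 higher and 595 lower with DESeq2 size factors, 936 and 753 by DESeq2, 797 and 613 with the stricter filter, 551 and 879 with none). CHAC1 rose 4.24-fold (log2 2.09 ± 0.16, adjusted p = 7.89e-16, edgeR), SLC7A11 2.71-fold and SLC6A9 2.58-fold. The transferrin receptor gene TFRC (log2 1.18), DDIT4 (1.18), CTH, which encodes a cysteine-producing enzyme (1.13), MT-RNR1 (1.04), DDIT3 (1.03), STC2 (0.97) and JDP2 (0.93) followed. MT-TQ (-4.25), MT-TP (-2.98), MT-ND6 (-1.83), MT-ND5 (-1.80), HSPA1B (-1.18), FGFBP1 (-1.13), HSPA8 (-0.96), CYP1A1 (-0.78), MT-ND3 (-0.78) and GLIPR1 (-0.77) fell most. Of 11 lists past the preset correlation 7 also passed with an estimated one. ATF4 targets had 28 up and 1 down of 32, 29 and 1 adjusted over the list alone (median 0.67, adjusted p = 3.52e-12 with an estimated correlation), and heat shock 11 of 22 down, 16 adjusted over the list alone (-0.23, 3.28e-06). Mitochondrially encoded mRNAs had 11 of 13 down (-0.36, 0.00895), oxidative phosphorylation 7 of 30 down (-0.14, 0.0338) and G1/S genes 6 of 34 down (-0.08, 0.01). Aryl hydrocarbon receptor targets had 3 of 9 down (-0.19, 0.0117) and nuclear-retained and non-coding RNAs 3 of 11 up (0.13, 0.00529). Without the low-detection libraries the oxidative phosphorylation list missed the threshold (adjusted p = 0.0926 with an estimated correlation). Lost with an estimated correlation were homologous recombination (adjusted p = 0.257), NF-kB targets (0.2), ribosomal proteins (0.21) and ribosome biogenesis (0.269). The immediate early gene EGR1, which encodes a growth-responsive transcription factor, fell to 45.5 CPM from 76.3 CPM in topotecan alone (log2 -0.70).

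Adding topotecan to OL9-119 changed 2415 genes, 949 higher and 1466 lower, and 2481 without the low-detection libraries. The excess of lower genes was smaller with DESeq2 size factors (1153 and 1349) and by DESeq2 (1365 and 1451). CXCL8 (log2 2.09 ± 0.14), CCL20 (1.93 ± 0.16), TNFAIP3 (1.64 ± 0.06), PTX3 (1.56) and TCIM (1.22) rose most, and TTC28 (-1.48 ± 0.08), NCKAP5 (-1.43), KCNQ5 (-1.34), MAML3 (-1.29) and FOXP2 (-1.26) fell most. Of 8 lists past the preset correlation 7 also passed with an estimated one. NF-kB targets had 18 of 22 up (median 0.67, adjusted p = 1.18e-10 with an estimated correlation), G2/M genes 24 of 30 down (-0.41, 1.05e-05), immediate early genes 15 up and 1 down (0.25, 0.000396), G1/S genes 13 up and 1 down (0.11, 3.93e-05) and p53 targets 12 up and 1 down (0.17, 1.05e-05). Interferon-stimulated genes had 7 up and 1 down of 30 (0.15, 0.00395) and sterol synthesis 5 up of 26 (0.06, 0.02). Splicing factors were lost with an estimated correlation (adjusted p = 0.0876). Of 1176 genes over 200 kb 643 fell and 2 rose, and the rank correlation with span was -0.33 across genes. With GC content it was -0.12, against 0.37 for topotecan minus DMSO, so the GC trend of topotecan alone did not recur here.

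Each compound's effect was thus measured in separate libraries without and with the other. Of the 1798 genes that passed with OL9-119 alone, 1710 (95.1%) had the same sign when topotecan was present, and 741 passed in both, all with the same sign. Of the 2913 genes that passed with topotecan alone, 2790 (95.8%) had the same sign when OL9-119 was present, and 1622 passed in both, 1621 with the same sign, against 371 expected. The correlation of log2 changes across genes, which are not independent replicates, was 0.24 (Pearson) and 0.27 (Spearman) for OL9-119 and 0.29 and 0.36 for topotecan. By clone, Pearson's r was 0.02 in C6, 0.29 in F7 and 0.11 in G6 for OL9-119, and 0.05, 0.24 and 0.25 for topotecan. Among the 9467 genes with a mean log2 CPM of at least 4, Pearson's r was 0.63 and 0.77.

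The interaction asks where the combination departs from the sum of both effects on the log2 scale. It passed for 6 genes by edgeR (1198 at unadjusted p under 0.05, 14 by DESeq2, 40 with no filter, 5 without the low-detection libraries). ATF3 and JUN, which each compound raised, rose less together than the sum. ATF3, a stress-induced transcription factor gene, stood at 145 CPM in DMSO, 275 in topotecan, 238 in OL9-119 and 302 in the combination (log2 -0.58 ± 0.05, adjusted p = 7.88e-12, edgeR). JUN (-0.52 ± 0.08, adjusted p = 0.000422, edgeR), DDIT3 (-0.51 ± 0.10) and ANKRD1 (-0.42 ± 0.09) had the same sign, and the nuclear import gene KPNA2 was above the sum (0.23 ± 0.05). Of 5 lists past the preset correlation 3 also passed with an estimated one. ATF4 targets were below the sum (median -0.26, 1 member of 32, 17 when adjusted over the list alone, adjusted p = 0.000381 with an estimated correlation), as were G1/S genes (no member of 34 over all genes or over the list alone, -0.11, 0.0216), and G2/M genes were above it (median 0.20, no member of 30 over all genes and 10 when adjusted over the list alone, adjusted p = 0.0014 with an estimated correlation). Immediate early genes (adjusted p = 0.214) and mitochondrially encoded mRNAs (0.556) were lost with an estimated correlation. Across 14685 genes the interaction had a rank correlation of -0.53 with GC content. It was -0.36 for DMSO minus no treatment and 0.37 for topotecan minus DMSO, which share the DMSO libraries with the interaction. The list tests did not hold GC content fixed, so they do not separate these departures from a GC trend.

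Topotecan and OL9-119 were both compared with the same DMSO libraries. They shared 536 passing genes, 240 higher in both, 146 lower in both and 150 opposite, where independent lists would share 50.9 higher and 88.7 lower. Their log2 changes correlated at 0.41 across genes, with a covariance of 0.0438. Unchanged groups simulated with the same controls gave a correlation of 0.531 (0.52 to 0.54) and a covariance of 0.0354. They had at most 2 calls for topotecan and 0 for OL9-119, so they give no comparison for the number of shared calls. With the DMSO libraries split between the comparisons by replicate, 271 and 293 genes were shared. Replicates 1 and 2, used for topotecan in the first split, held all 3 low-detection DMSO libraries (C6 replicates 1 and 2, G6 replicate 1). Against them topotecan gave 3565 calls and OL9-119 2011, and against replicates 3 and 4 they gave 1679 and 945. The split is thus mixed with low gene detection. In the first split 114 were higher in both (38.2 expected), 51 lower in both (50.9 expected) and 106 opposite, and in the second 110 (33.8 expected) and 79 (50.7 expected), with the rest of the 293 opposite. The correlations were 0.03 and 0.07 and the covariances 0.00694 and 0.0137.

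DMSO against no treatment measures the vehicle and serves as background. It changed 3 genes, all lower: the glucose transporter gene SLC2A3 (log2 -0.35 ± 0.06, adjusted p = 0.0145, edgeR), IER3 (-0.32 ± 0.06, adjusted p = 0.0225, edgeR) and the metalloprotease gene ADAMTS1 (-0.19 ± 0.03, adjusted p = 0.0145, edgeR). At unadjusted p under 0.05 there were 953 genes, and DESeq2 called 16. Without the low-detection libraries edgeR called 0. HIF1 targets and glycolysis were lower (1 member of 30, 9 when adjusted over the list alone, median -0.17, adjusted p = 0.00152 with an estimated correlation) and the unfolded protein response was higher (no member of 24 over all genes, 1 adjusted over the list alone, median 0.06, adjusted p = 0.0263 with an estimated correlation). Without the low-detection libraries these stood at 0.126 and 0.411 with an estimated correlation. Ribosomal proteins (adjusted p = 0.698), extracellular matrix (0.0726) and neuronal and renal lineage genes (0.215) were lost with an estimated correlation. The change had a rank correlation of -0.36 with GC content across genes.

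The response to topotecan differed between clones for 26 genes (47 by DESeq2, 52 without the low-detection libraries, 11 without replicate 3), with clone F7 responding least among the clearest. TNFAIP3 rose by log2 2.57 in C6, 0.50 in F7 and 2.35 in G6 (adjusted p = 3.81e-16 for the difference, edgeR). It went from 16.3 ± 2.28 to 97.7 ± 13.1 CPM in C6, from 57.7 ± 5.35 to 81.5 ± 4.02 CPM in F7 and from 27.9 ± 3.01 to 143 ± 11.1 CPM in G6 (SD, n = 4). CXCL8 rose by 3.43, 0.93 and 3.34 in C6, F7 and G6 (adjusted p = 3.53e-07, edgeR), ATF3 by 1.38, 0.29 and 1.14 (1.5e-13), and IER3 by 1.38, 0.41 and 1.74 (6.54e-08). AURKA changed by -1.29, -0.38 and -0.88 (adjusted p = 5.86e-07, edgeR). The NF-kB targets had medians of 1.07 in C6, 0.24 in F7 and 1.00 in G6, with 7 of 22 depending on the clone, and the G2/M genes -0.80, -0.31 and -0.67, with 5 of 30 doing so. In DMSO clone F7 stood above both other clones for 15 of the 22 NF-kB targets. The response to OL9-119 differed for 5 genes in the fit of all libraries, and for 0 in a fit of only the groups compared and 0 without replicate 2 or 3. All 100 splits of the libraries reached that 0, as any count does, so they do not test it. The 5 were HERPUD1 (log2 1.19, 0.57 and 1.22 in C6, F7 and G6) and DDIT3 (1.89, 0.97 and 1.78), both with adjusted p = 0.00699 by edgeR, HSPA8 (-1.44, -1.01 and -0.81), CCN1 (-0.56, -0.28 and -1.11) and ADAMTS1 (0.51, 0.15 and 0.10). The response to the combination differed for 32 genes (52 by DESeq2, 36 without the low-detection libraries, 9 without replicate 3), led by TNFAIP3 (adjusted p = 4.52e-15, edgeR), the syndecan gene SDC4 (0.72, -0.09 and 0.74), ATF3, IER3 and NFKBIA.

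**Figure D4:**
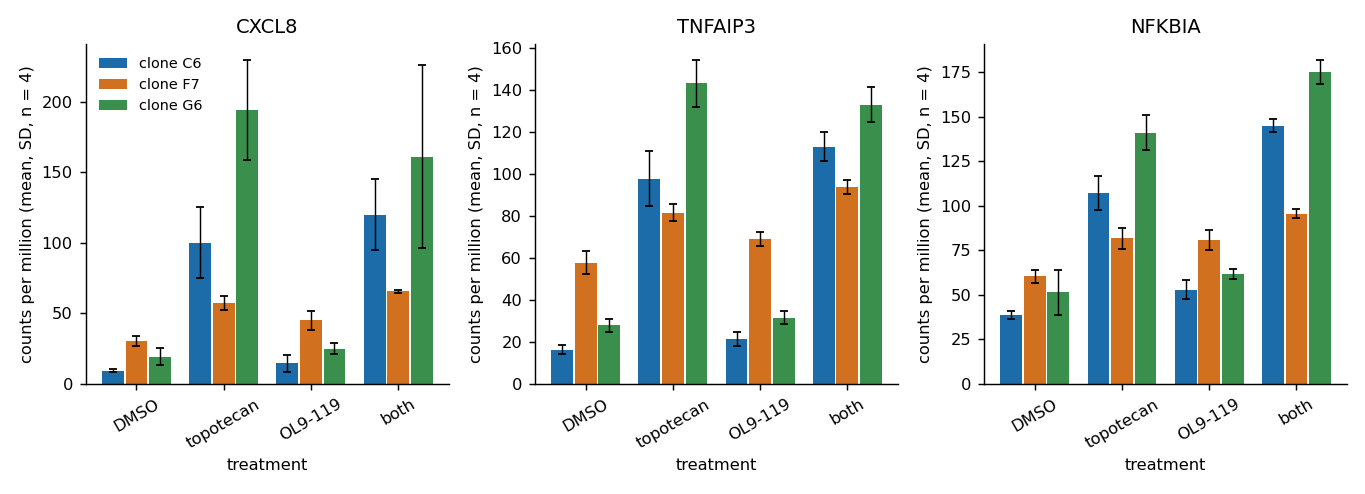
CXCL8, TNFAIP3 and NFKBIA in CPM (linear axes from 0) by treatment and clone, as bars at the mean of 4 replicates with SD. TNFAIP3 goes from 16.3 CPM in DMSO to 97.7 CPM in topotecan in C6, from 57.7 to 81.5 CPM in F7 and from 27.9 to 143 CPM in G6.

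The 3 clones were compared with each other in DMSO, which asks how far clones of one knockout differ without a drug. Between C6 and F7 7508 genes passed (3871 higher and 3637 lower in C6), between C6 and G6 4635 (2199 and 2436), and between F7 and G6 3241 (1309 and 1932). With the low-detection libraries left out, these were 8209, 4972 and 4638. In fits of only the 2 groups compared they were 7376, 2370 and 3084. Which side of C6 against F7 held more genes depended on the scaling and the filter: 3469 were higher and 4002 lower with DESeq2 size factors, 3593 and 4277 by DESeq2, and 3264 and 3883 with no filter. For F7 against G6 the excess of lower genes was smaller with DESeq2 size factors (1494 and 1584) and by DESeq2 (1750 and 1760). Some genes were counted in one clone and near 0 in another. SOX11, a neural transcription factor gene (chromosome 2, 5692667 to 5701385), stood at 0.199 ± 0.0582 CPM in C6, 38.3 ± 2.79 in F7 and 35 ± 7.03 in G6 (SD, n = 4). PLBD1, a phospholipase-like gene, stood at 15.4 ± 2.39, 0.0662 ± 0.05 and 0.0135 ± 0.0269 CPM. ZNF532 and CHRDL1 were near 0 in C6 (0.664 and 0.817 CPM) and at 28.7 and 30.2 CPM in F7. MYD88, an adaptor of Toll-like receptors, stood at 20.4, 4.51 and 0.378 CPM in C6, F7 and G6, the collagen gene COL2A1 at 33.9, 2.21 and 0.923 CPM, the collagenase gene MMP1 at 1.79, 23.8 and 20.3 CPM, the E-cadherin gene CDH1 at 3.48, 13.7 and 1.26 CPM, and the autophagy kinase gene ULK2 at 43.4, 3.14 and 26 CPM. GALC (chromosome 14, 87837820 to 87993665), a lysosomal enzyme gene on the same arm as TDP1, stood at 5.5 ± 3.1, 6.68 ± 0.51 and 0.113 ± 0.108 CPM.

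Of the gene lists, 6 passed both correlations for C6 against F7, 1 for C6 against G6 and 5 for F7 against G6. NF-kB targets were lower in C6 than in F7 (16 of 22 down, median -0.99, adjusted p = 0.004 with an estimated correlation) and higher in F7 than in G6 (12 up and 1 down, 0.65, 0.000936). Ribosome biogenesis genes were lower in C6 than in F7 (19 of 30 down, -0.42, 0.0207) and higher in F7 than in G6 (15 up and 1 down, 0.39, 0.0153). Replication-dependent histones, whose copies share sequence so that their reads are uncertain, were lower in C6 than in F7 (9 of 17 down, -1.01, 0.0207) and higher in F7 than in G6 (5 of 17 up, 0.78, 0.0113). G1/S genes were higher in C6 than in F7 (20 up and 5 down of 34, 0.36, 0.00712) and lower in F7 than in G6 (1 up and 14 down, -0.19, 0.00139). Immediate early genes were lower in C6 than in F7 (1 up and 19 down of 30, -0.57, 0.0207). The unfolded protein response was lower in F7 than in G6 (2 up and 11 down of 24, -0.25, 0.000989). Nuclear-retained and non-coding RNAs were lower in C6 than in F7 (median -0.66, 0.0182) and than in G6 (-0.49, 0.018). The other lists that passed with the preset correlation were lost with an estimated one, 5 for C6 against F7, 9 for C6 against G6 and 8 for F7 against G6.

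Chromosome medians differed between the clones. A median does not show whether a whole chromosome or a part of it differed. Of 69 chromosome medians, 42 passed the threshold against random gene sets of the same size (permutation, 2-sided, adjusted by Benjamini-Hochberg), many at a p of 1e-04, the smallest that 10000 random sets can give. Some of the 42 were small, such as 0.00 for chromosome 12 in C6 minus F7. The median of 510 genes on chromosome 20, which carries TOP1, was lower in C6 than in F7 (log2 -0.67, 0.628-fold) and than in G6 (-0.58, 0.671-fold). That of 1039 genes on chromosome 11 was -0.54 against both. Chromosome 16 was lower in C6 than in F7 (-0.38). Chromosome 13 was higher in C6 than in F7 (0.52, 1.43-fold) and G6 (0.30), chromosome 7 higher in C6 than in G6 (0.35), and chromosome 21 higher in C6 than in F7 (0.31) and G6 (0.36). Chromosome 14, which carries TDP1, was higher in C6 than in F7 (0.29) and lower in F7 than in G6 (-0.29). Of the 42 shifts, 33 also passed with the same sign in untreated libraries and 37 without the low-detection libraries.

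**Figure D5:**
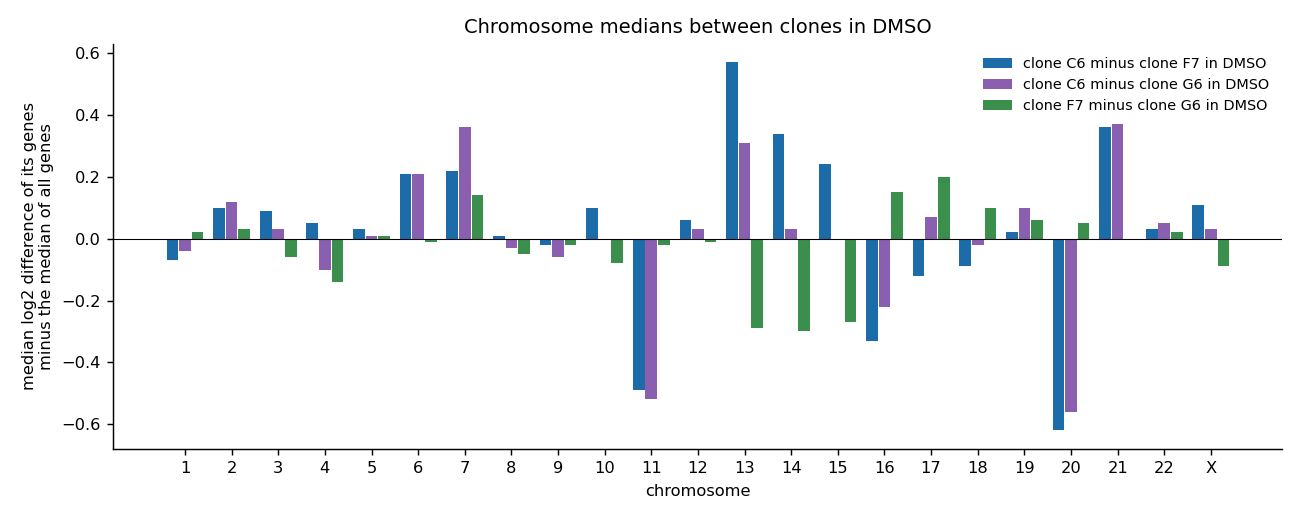
Median log2 difference of the genes on each chromosome minus the median of all genes, as bars for the 3 pairs of clones in DMSO. Chromosome 20 lies at -0.62 for C6 minus F7 and at -0.56 for C6 minus G6.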

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

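Of the tests in this part, the count of span slopes and the comparison of mitochondrial strands were written after their results were seen, and every test without the 14 libraries of low gene detection uses an alternative added after seeing the data.

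Of 75 groups and measures tested for a library far from its 3 replicates, 3 were picked out, and chance flags about 1 in 20 groups. The combination library of clone F7, replicate 2, held 13.8 M counts against 8.17 to 9.12 M counts in the others. In clone G6, untreated replicate 1 had 19200 genes detected at equal depth against 21900 to 22200, and OL9-119 replicate 1 had 18500 against 22000 to 22500.

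The response to a treatment differed between clones by a direct test (edgeR quasi-likelihood, adjusted p). For topotecan 26 genes did so, with the smallest adjusted p by edgeR for TNFAIP3 (3.81e-16), ATF3 (1.5e-13), IER3 (6.54e-08), CXCL8 (3.53e-07) and AURKA (5.86e-07). For OL9-119 5 did so in the fit of all libraries and 0 in a fit of only the groups compared: HERPUD1 (adjusted p = 0.00699, edgeR), DDIT3 (0.00699), HSPA8 (0.0089), CCN1 (0.029) and ADAMTS1 (0.0354). For the combination 32 did so, first TNFAIP3 (adjusted p = 4.52e-15, edgeR), SDC4 (7.99e-09), ATF3 (3.16e-08), IER3 (5.75e-08) and NFKBIA (6.75e-08).

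Splits that mix the libraries of the groups compared tested whether any division of the same libraries gives as many calls. Topotecan minus DMSO gave 3096 calls in a fit of its own groups and at most 210 in the others, so that 1 of 100 splits, the real one, reached it. The combination minus DMSO gave 3615 (highest other 150, 1 of 100), minus topotecan 1662 (62, 1 of 100) and minus OL9-119 2128 (2, 1 of 100). C6 minus F7 gave 7376, C6 minus G6 2370 and F7 minus G6 3084, each with a highest other of 0 and 1 of 35 splits reaching it. For these 7 only the real split reached its count, the smallest share that 100 or 35 splits allow. It lies under the 5 of 100 set in advance for chance. Mixing 2 groups adds their difference to the spread within each, so the other splits tend to few calls. OL9-119 minus DMSO gave 1352, and 2 of 100 splits reached it, the real one and another with 4393 calls, fewer than the 5 of 100 set in advance for chance. That other split put all 6 low-detection libraries on 1 side, which points to a structure of the samples. The same holds for DMSO minus no treatment, where the highest other (6453) had all 5 low-detection libraries on 1 side. Its real split gave 0 calls, which all 100 splits reach whatever the data, so they cannot exclude chance there and do not test it. The interaction gave 4 (highest other 281, 2 of 100 reaching it), the clone dependence of topotecan 22 (1206, 3 of 100) and that of the combination 11 (1454, 3 of 100), all under 5 of 100. Their highest splits gave several times the real count, which points to a structure of the samples, though low-detection libraries stood on both sides there (4 and 8, 1 and 4, and 2 and 5), and what the structure is was not tested. The clone dependence of OL9-119 gave 0 in this fit, and the highest other was 2723. All 100 splits reached 0, as any count does, so the splits cannot exclude chance for it and do not test it.

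Long genes had lower counts after topotecan, with a rank correlation of -0.49 with genomic span. Exon length, exon number, GC content and expression level do not account for all of it, since the partial rank correlation with these 4 held fixed was -0.28. The low-detection libraries do not account for it either, since without them the correlation was -0.47. A response to topotecan would lower the slope in each clone and replicate, and 12 of 12 slopes lay below 0, a test written after the result was seen that largely restates it, with 8 of 12 background slopes (DMSO minus untreated) below 0 as well. The background slopes use the same DMSO libraries with opposite sign, so they are not independent of the topotecan slopes. Slower or interrupted elongation and faster decay of long transcripts remain open, because poly(A) counts do not separate them.

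Mitochondrial genes annotated on the minus strand had a lower median after OL9-119 than those on the plus strand, though MT-ND5 (-2.06) and MT-TT (-3.34) on the plus strand fell further than MT-ND6 (-1.68). A loss of all mitochondrial counts alike is argued against by the difference of the strand medians, -3.42 on the log2 scale (written after the result was seen), and by the rise of MT-RNR1 (0.75). Both rest on poly(A)-enriched counts, which do not separate the amount of an RNA from its capture, so a change in capture stays open too. The low-detection libraries are argued against by a minus-strand median of -3.92 without them. Reduced transcription of that strand, a difference by RNA type (6 of the 7 are transfer RNAs and all fell, by 2.34 to 5.55, while of the 3 on the plus strand MT-TT fell and MT-TI and MT-TW, near 1 CPM, did not pass), and an unknown strand setting in the counting, which could mix reads of both strands at MT-ND5 and MT-ND6, stay open.

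NF-kB targets rose less in clone F7 than in both other clones after topotecan for 21 of 22 members. Low-detection libraries, none of which is in F7, are argued against, since 21 of 22 still rose less in F7 without them (medians 0.89 in C6, 0.23 in F7 and 1.09 in G6). F7 stood above both other clones in DMSO for 15 members, so it might start near the level the others reach. In topotecan it lay below both for 12 of 22 members and above both for 9, so this and a weaker response of F7 cannot be told apart with 1 time point and 1 dose.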

How the results depend on the processing

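Of 437 named gene values, 426 passed the threshold and 296 of these passed in every setting run. The sign reversed for 2, both with untreated libraries in place of DMSO: HSPA5 after topotecan (0.02) and NEFL after the combination (-0.01). Stricter filtering, DESeq2 size factors and the library code prefix left every count of genes within 1.5 times, and size factors shifted medians by at most 0.042 in absolute log2 change. With no filter DMSO minus no treatment gave 13 genes, the interaction 40 and the clone dependence of OL9-119 9. DESeq2 gave 16 and 14 for DMSO minus no treatment and the interaction, and 47, 8 and 52 for the clone dependence of topotecan, OL9-119 and the combination. With untreated libraries as control the clone dependence of OL9-119 gave 3. In fits of only the groups compared, DMSO minus no treatment gave 0, C6 minus G6 2370, and the clone dependence of OL9-119 and of the combination 0 and 11. With 2 clones, topotecan gave 1912 without F7 and 1555 without G6. OL9-119 gave 1136, 843 and 1078 without C6, F7 and G6. The combination gave 2479 minus DMSO without F7, 675 and 273 minus topotecan without C6 and F7, and 1560 and 1493 minus OL9-119 without F7 and G6. DMSO minus no treatment gave 0 with any 2 clones, and the interaction 2, 3 and 1 without C6, F7 and G6. Fewer libraries were tested there. Without the low-detection libraries (chosen after seeing the data) OL9-119 gave 2820, DMSO minus no treatment 0 and the clone dependence of topotecan 52. For gene span the correlation was -0.29 with exon length and -0.36 with exon number in place of span, -0.63 among genes with log2 CPM of at least 4 and -0.42 against untreated libraries. The effect of OL9-119 with and without topotecan correlated at 0.63 among the higher genes, and at a threshold of 0.01 the overlap of topotecan and OL9-119 was 247 genes. Of 210 tests of gene lists, an estimated correlation ended the call of 21, fry ended 7 and added 22, and leaving out the low-detection libraries ended 11 and added 6. Except where libraries or genes were fewer, the cause was not tested.

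With a replicate block (clone by replicate number) topotecan gave 3843 genes, OL9-119 2600, the combination 4931 minus DMSO, 2455 minus topotecan and 3280 minus OL9-119, DMSO minus no treatment 11 and the interaction 14. The numbers were not taken to pair the libraries: 46 of 120 same-numbered pairs correlated over 0.1 (-0.287 to 0.443), and 30 of 60 libraries correlated best with their own number, not every one, but more than the 1 in 4 of chance. Low gene detection also followed the number in part: 8 of the 14 libraries were replicate 1, all 4 of those in G6 among them, and none was replicate 3. The prefix of the library code is the same over all treatments of a clone and replicate number, and the labels do not say what it marks.

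Leaving out a replicate number or a single library gave 1872 to 3406 genes for topotecan, 858 to 2039 for OL9-119, 2677 to 4184 for the combination minus DMSO, 513 to 1814 minus topotecan and 1499 to 2622 minus OL9-119. It gave 0 to 11 for DMSO minus no treatment, 1 to 9 for the interaction, 5184 to 7922 for C6 minus F7, 3168 to 4904 for C6 minus G6 and 1498 to 4325 for F7 minus G6. The clone dependence went from 11 to 31 for topotecan, 0 to 6 for OL9-119 and 9 to 43 for the combination, and the overlap of topotecan and OL9-119 calls from 207 to 410 genes without 1 replicate number. Single libraries moved a count by over 1.5 times in F7 minus G6 (2148 without G6 DMSO replicate 1), in the clone dependence of the combination (21 without F7 combination replicate 2), and in the counts of at most 6 genes.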

Other observations

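Genes around TDP1 on chromosome 14 differed between clones. The median of the chromosome differed too, over 573 genes at 0.29 for C6 minus F7 and -0.29 for F7 minus G6. Over all chromosomes 7508 of 18985 genes passed for C6 minus F7, so an effect local to TDP1 is not shown. PSMC1, a proteasome gene past TDP1, was higher in C6 than in F7 (log2 0.62, adjusted p = 5.64e-08, edgeR) and lower in F7 than in G6 (-0.51, adjusted p = 1.43e-05, edgeR). ZC3H14 (0.52), FOXN3 (0.76), NRDE2 (0.48) and EML5 (1.51) were among the others higher in C6 than in F7, and LGMN (-0.37) and CHGA (-1.17) were lower. GALC was near 0 in G6 (0.113 CPM).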
